A study of Arabidopsis thaliana with 8 samples.

How the data were processed

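Small RNA from Arabidopsis thaliana inflorescences was sequenced in 8 libraries, 1 each for wild type (WT, Col-0), the single mutants drb1, drb2 and drb4, the double mutants drb12, drb14 and drb24, and drb35, which lacks DRB3 and DRB5. DRB proteins bind double-stranded RNA and work beside the Dicer-like enzymes that make small RNA. Per the labels' protocols, plants grew on soil in long days of 16 h light and 8 h dark at 23 °C by day and 18 °C by night, after stratification at 4 °C, and total RNA was extracted with TRIzol and size-fractionated. The deposited unit is the count: each file lists distinct sequences of 16 to 35 nt with the raw number of reads of each. Per the submitters' processing notes the genome build was TAIR10. The adapter trimmer, the aligner and any abundance filter of the authors are not given in the sources used here.

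Every sequence of 16 to 32 nt was matched without mismatch to the reference genome TAIR10.1, and 86.4 to 90.3% of those reads matched. Library size was the number of reads of 20 to 25 nt (25161996 in drb14 to 40614669 in drb2), and levels are reads per 1000000 of these (RPM). The level that 3 reads give, taken as the floor for a count of 0, was 0.0739 to 0.119 RPM. Mature miRNAs were counted by exact sequence. A list of 144 sequences was written down in advance: 47 conserved miRNAs, 52 less conserved miRNAs, 3 DCL4-dependent miRNAs (made by DICER-LIKE 4 in place of DCL1, as listed in advance), passenger strands, trans-acting siRNAs (ta-siRNAs) and repeat siRNAs. Of these, 1 had no genome match and 1 was a duplicate, which left 102 guides and 34 passengers. Reads over 50 fixed loci (8 TAS loci, which give ta-siRNAs, loci in pentatricopeptide repeat (PPR) genes, other phased siRNA loci, the DRB genes and small RNA pathway genes) were divided by their number of genome positions. Other lists read were copper, phosphate and sulphate, phase-change and pollen miRNAs, the last as a sign of tissue make-up, and tRNA, rRNA, snoRNA and organelle fragments as a sign of RNA quality. Windows of 1000 nt were counted from reads with 1 genome position, for 24 nt and for 21 and 22 nt. A window was placed in a coding exon, another part of a protein-coding gene, a pseudogene, a MIR gene, another gene or no annotated gene. Windows that touch a MIR gene were also counted apart from these.

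With 1 library per genotype, no genotype has a replicate. Each allele is repeated across backgrounds: DRB1 was mutated in drb1, drb12 and drb14, DRB2 in drb2, drb12 and drb24, and DRB4 in drb4, drb14 and drb24, each set of 3 against the other 5. Counts were fitted with an additive model (terms for DRB1, DRB2, DRB4 and DRB3 with DRB5) in edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with 3 residual degrees of freedom that hold interactions and noise together. The term for DRB3 and DRB5 rests on 1 library and was not tested. Sequences, loci and windows with at least 10 reads in at least 3 libraries entered (76 guides, 40 loci for 21 and 22 nt, 29 loci for 24 nt, 30788 windows for 24 nt and 15548 for 21 and 22 nt). Calls were made at a Benjamini-Hochberg false discovery rate (FDR) of 0.05 over each set. Standard errors (SE) were the size of the log2 change divided by the square root of the F statistic. Values per library (size classes and the like) were compared with two-sided exact permutation tests over the 56 ways to pick 3 of 8 libraries, with 21 tests in the family. Pairs of genotypes were compared as ratios of RPM with exact conditional 95% intervals, which cover counting error only. List medians were placed among 10000 random lists matched on mean level in 4 bins.

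These choices, the lists and the comparisons were made before the data were examined, and so was the rule for named genes. That rule takes the DCL4-dependent miRNAs, the TAS loci and the ta-siRNA triggers miR173, miR390a and miR828 where they pass the count filter. Per allele it takes up to 10 rising and 10 falling miRNAs that pass the test and move the same way in all 3 matched pairs (for DRB1, drb1 over WT, drb12 over drb2 and drb14 over drb4), by size. Per mutant against WT it takes the 5 guides with the most WT reads and the 5 highest and 5 lowest ratios with at least 100 reads in 1 of the 2 libraries. Per allele and length class it takes the 5 windows that rise and the 5 that fall most, past the test and the same way in all 3 pairs. The 5 DRB genes come first. The fit of 24 nt reads over the fixed loci and the alternatives for both locus fits were added after the data were seen, as was a library size of tRNA, rRNA, snoRNA and organelle reads for every fit.

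Passenger and guide reads were compared with a pseudocount of 0.5 in the 26 pairs with enough passenger reads, and 28 of the 34 passenger sequences are themselves annotated mature sequences. The share of reads at the annotated 5′ end was taken among reads within 5 nt of it, for miRNAs with at least 100 such reads. Reads of a MIR precursor more than 2 nt from an annotated end were counted as off register. The alternatives were TMM and DESeq2 size factors, other library sizes, reads with ends within 2 nt (19 to 24 nt), other count minima (30 reads for windows), windows of 500 nt, weighted multi-mapped reads, DESeq2 1.42.0 (Wald test), 2 groups without covariates, matched backgrounds as blocks, and leaving out each library. The fit was tested on simulated data: 2-fold changes were recovered for 60, 40 and 40% of changed miRNAs (DRB1, DRB2, DRB4) and 4-fold changes for 100%. In windows of 24 nt reads, 2-fold changes were recovered for 46.9 to 54.5% and 4-fold changes for 95.8 to 97.0%. In windows of 21 and 22 nt reads the ranges were 25.8 to 34.4% and 84.8 to 92.8%. Each miRNA percentage rests on 10 changed miRNAs. The simulated changes went up and down alike and held no interactions between alleles. The recovery may therefore differ in the real data, where most miRNAs fell together with DRB1 or DRB2 mutated. Label deals, in which the library labels were dealt anew, numbered 100 for miRNAs and loci and 60 for windows, with the real labels counted as 1 of them. Other deals that left the tested allele on its own libraries were not counted. Other tools were limma 3.58.1 (called by edgeR), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Sequences without a genome match were not assigned to any source, and no messenger RNA was measured, so the genotype labels could not be checked from transcript levels.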

Results

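The 8 inflorescence libraries held 35350301 (drb14) to 46407657 (drb2) reads, and WT 38418895. Each genotype has 1 library, so a value for a genotype has no replicate, and a test exists only for an allele across backgrounds: DRB1, DRB2 or DRB4 mutated in 3 libraries against 5. The smallest level that could be told from 0 was about 0.1 RPM in every library (0.0739 to 0.119 RPM for 3 reads).

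The 5 DRB genes gave few small RNA reads in WT, and several mutants stood apart. Over DRB1 (AT1G09700), the partner of DCL1, 21 and 22 nt reads numbered 151 in drb1 and 15 in drb14 but 2 in drb12 and 4 in WT. Reads of 24 nt over DRB1 stood at 4.53 RPM in drb14 against 0.0332 in WT. Over DRB4 (AT3G62800), the partner of DCL4, 24 nt reads numbered 33 in drb14, 8 in drb4, 8 in drb24 and 0 or 1 in the other 5 libraries, and 21 and 22 nt reads numbered 0 to 9 in each library. Over DRB3 (AT3G26932), drb35 had 93 reads of 24 nt and WT 2. Over DRB5 (AT5G41070), 24 nt reads stood at 5.13 RPM in drb4, 6.28 in drb14 and 1.98 in drb24, against 0.0996 in WT and 0.238 in drb35. Over DRB2 (AT2G28380), 21 and 22 nt reads numbered 2 in WT and 16 in drb14, and 24 nt reads 6 in WT and 61 in drb14. Small RNA over a gene is not a measure of its transcript, so these values do not check the genotype labels.

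Reads of 24 nt, the length of siRNAs from repeats, were the most frequent class. They took 38.5% of all reads in WT, 51.1% in drb2, 49.9% in drb12 and 54.6% in drb24, and 35.5 to 41.9% in the other 4 libraries. Reads of 21 nt, the length of most miRNAs, took 18.4% in WT, 20.4% in drb35 and 19.7% in drb4, and 8.79 (drb24) to 16.0% (drb14) in the remaining 5. With DRB2 mutated the mean 24 nt share was 51.9% (SD 2.45, n = 3) against 38.3% (SD 2.30, n = 5; two-sided exact permutation p = 0.0179, the smallest that 3 against 5 can give; BH-adjusted p = 0.0938 over 21 tests). The 22 nt share with DRB4 mutated was 4.35% (SD 0.546, n = 3) against 6.36% (SD 0.308, n = 5; two-sided exact permutation p = 0.0179, adjusted 0.0938). Fragments of structural RNA were 5.69% (SD 0.963, n = 3) with DRB2 mutated and 10.3% (SD 1.82, n = 5) otherwise, and organelle fragments 3.55% and 6.53% (two-sided exact permutation p = 0.0179 for both, adjusted 0.0938). In each of these comparisons the 3 libraries lay outside the range of the other 5, and no test of the 21 passed 0.05 after adjustment.

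**Figure D1:**
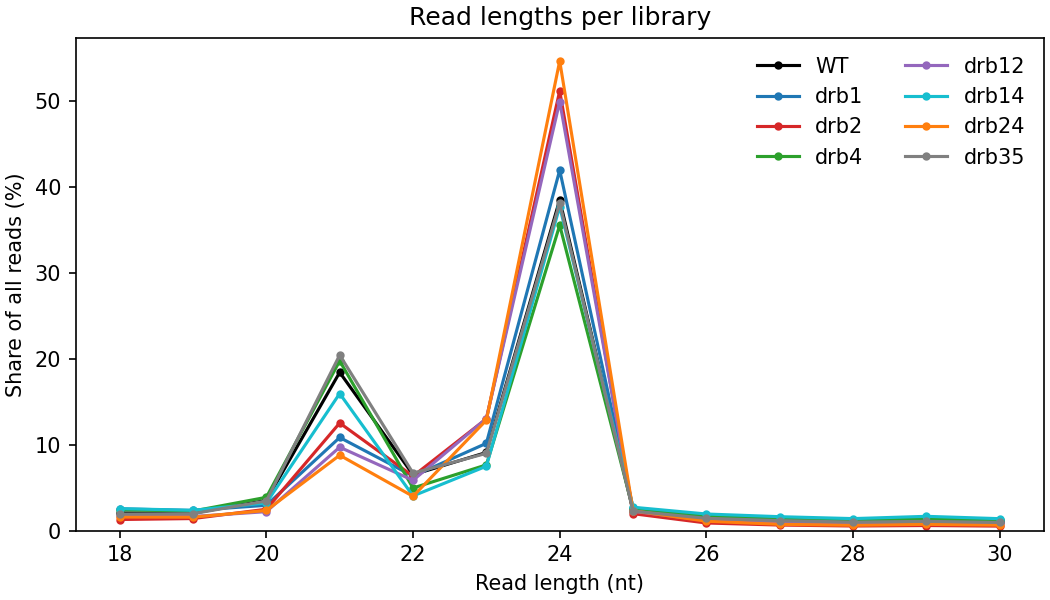
Share of all reads (percent) at each read length from 18 to 30 nt, with 1 line per library. At 24 nt, drb24 (54.6%), drb2 (51.1%) and drb12 (49.9%) lie above WT (38.5%), and at 21 nt, WT (18.4%), drb4 (19.7%) and drb35 (20.4%) lie above the other 5.

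With DRB1 mutated, most miRNAs were lower. Of 76 tested, 57 fell and 1 rose (edgeR, FDR 0.05), with a median log2 change of −1.81. The largest falls were miR173, the trigger of TAS1 and TAS2 siRNAs (log2 −5.26, SE 0.30, FDR 5.39e-06), miR781a (−5.25, SE 0.35, FDR 8.03e-06), miR853 (−5.15), miR838 (−4.79), which lies in the DCL1 transcript, and miR162a (−4.69, SE 0.34, FDR 9.25e-06), which targets DCL1. miR848 (−4.30), miR159a, which targets GAMYB-like MYB genes (−4.20), miR860 (−3.94), miR319c, which targets TCP genes (−3.47), and miR771 (−3.36) followed. miR173 stood at 15.7 RPM in WT and at 0.42, 0.204 and 0.358 in drb1, drb12 and drb14, and miR162a at 599 against 18.5, 14.01 and 37.8. All 10 kept their call and direction with TMM, under which the median of all 76 was −0.21 (miR173 −3.66, miR159a −2.59). miR840 rose (0.97, SE 0.33, FDR 0.0241; 2.59 with TMM). Its call was lost without WT (0.98), drb1 (1.13), drb4 (1.01), drb12 (0.92) or drb14 (0.85), with end variants (0.38), with structural reads as library size (0.67) and with 2 groups (0.99). miR390a, the trigger of TAS3, fell (−0.80, SE 0.29, FDR 0.0313) but less than the median, and was higher under TMM (0.81, FDR 0.0259). Its call was lost without WT (−0.74), drb1 (−0.64), drb2 (−0.66), drb4 (−0.86) or drb12 (−0.76) and with 2 groups (−0.68). With TMM 18 rose and 21 fell, and 22 of the 58 calls were kept in direction. TMM scales by the typical change of the miRNAs themselves, which moves the median toward 0 by construction. It does not decide whether miR390a rose. With DESeq2 size factors 20 rose and 19 fell, and with 2 groups and no covariate 37 passed.

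By list, 31 of 38 less conserved miRNAs fell and 1 rose (15 and 7 with TMM). Of the conserved miRNAs 26 of 36 fell (6 fell and 9 rose with TMM). Adjusted over the list alone these counts were the same. For the DCL4-dependent miRNAs with enough reads the term of DRB1 did not pass, miR822 at −0.18 (FDR 0.688) and miR839 at −0.28 (FDR 0.622). Against WT (39.6 RPM) miR839 stood at 53.4 RPM in drb1 but at 14.97 in drb12 and 2.46 in drb14. edgeR called 0 of them (0 at unadjusted p under 0.05; DESeq2 called 0), and with TMM 2 rose (1.45 and 1.34). Both copper miRNAs tested, miR398b and miR408, fell (−2.47 and −1.67; with TMM edgeR called 0, 0 at unadjusted p under 0.05, and DESeq2 called 2 at the main library size). So did 5 of 6 phase-change miRNAs of the miR156, miR157 and miR172 families (1 with TMM) and both pollen miRNAs, miR845a (−1.74) and miR845b (−2.69; 1 with TMM). Of 6 phosphate and sulphate miRNAs 2 fell, miR827 (−0.75) and miR399b (−0.89), with 0 adjusted over the list alone and 3 upward with TMM. The counts adjusted over the list alone were otherwise the same.

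**Figure D2:**
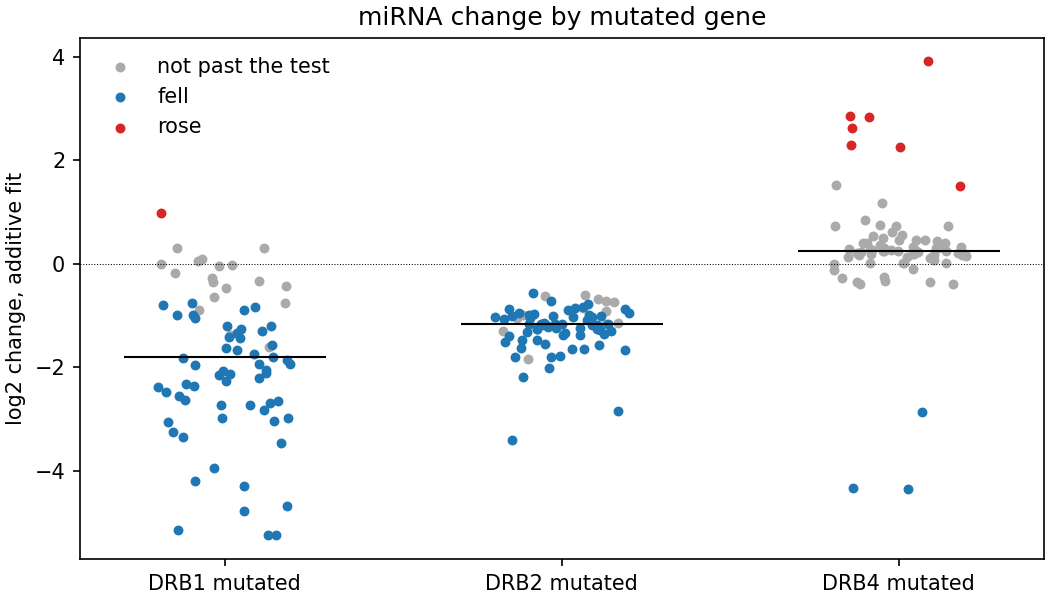
Log2 change of each of the 76 tested miRNAs (points) with DRB1, DRB2 or DRB4 mutated; blue fell and red rose past FDR 0.05, grey did not pass, and the horizontal line is the median (−1.81, −1.17 and 0.25). With DRB1 and DRB2 mutated most points lie below 0, a shift that TMM takes to −0.21 and −0.03, and with DRB4 mutated 7 rose and 3 fell.

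At fixed loci, 21 and 22 nt reads fell at 7 of 8 TAS loci with DRB1 mutated. These included the 4 that miR173 triggers, TAS1B (log2 −4.61, SE 0.29, FDR 1.13e-06), TAS1A (−3.88, SE 0.27), TAS2 (−3.09, SE 0.21) and TAS1C (−2.17, SE 0.18), and TAS4, which miR828 triggers (−3.78, SE 0.98, on 36 reads in WT). TAS3A, which miR390 triggers and whose siRNAs target auxin response factors, was at 0.11 (SE 0.14, FDR 0.511). TAS3B (−0.94) and TAS3C (−0.82, FDR 0.0359) fell by less than the median locus (−2.25). Of 16 PPR loci 15 fell, of 10 other phased loci 4, and of 3 pathway genes 1 (DCL1, −2.23). Among the DRB genes DRB2 rose (1.26, 2 to 16 reads per library; DESeq2 called 0 DRB genes). In all 27 of 40 loci fell and 1 rose, with the same counts adjusted over the list alone. With TMM the median locus moved to 0.01, 11 fell and 16 rose. TAS1B (−2.33), TAS1A (−1.60) and TAS2 (−0.81) stayed lower with TMM, TAS1C was at 0.11, and TAS3B (1.34), TAS3C (1.47) and TAS3A (2.39) were higher. TMM was computed from these loci, most of which fell, so it does not decide whether the TAS3 loci rose. The call of TAS4 was lost without WT (−3.49), and that of TAS3C without WT (−0.72), drb1 (−0.92), drb4 (−0.90) or drb12 (−0.74).

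Reads of 24 nt fell with DRB1 mutated at 5 of 7 TAS loci: TAS1B (−5.38, SE 0.49, FDR 7.13e-17), TAS1A (−5.37, SE 0.48), TAS2 (−3.99), TAS1C (−3.08) and TAS3B (−1.13). They also fell at 8 of 10 PPR loci and at 2 of 7 other phased loci, AT1G12290 and AFB3. At the 3 DRB genes and 2 pathway genes edgeR called 0 (0 at unadjusted p under 0.05; DESeq2 called 0). In all 15 of 29 loci fell (8 with TMM, 9 without WT, 8 without drb12), with the same counts adjusted over the list alone. The call of TAS3B was lost with TMM (−0.25), with matched backgrounds as blocks (−1.12) and without WT (−1.30), drb4 (−1.16), drb12 (−0.93) or drb24 (−1.12). Among windows of the whole genome, 26 rose and 21 fell of 30788. In AT5G45170, a haloacid dehalogenase-like gene (chromosome 5, 18273001 to 18274000), 24 nt reads stood at 72.3 RPM in drb1 and 79.3 in drb12, 2.03 in drb14 and 0.0664 in WT (FDR 9.45e-05). A window without an annotated gene (chromosome 5, 19830001 to 19831000) had 32.7, 46.01 and 7.19 RPM in drb1, drb12 and drb14 and 0.0332 in WT (FDR 9.45e-05). The window of TAS1A (chromosome 2, 11721001 to 11722000) fell from 16.3 RPM in WT to 0.27, 0.0874 and 1.23 (FDR 0.00111). The count of 47 became 17 without WT, 85 without drb1, 104 without drb4, 16 without drb12 and 435 without drb24. It was 74 with TMM (28 up), 463 with DESeq2 and 433 with blocks. It was 149 with structural reads as library size, 90 with 500 nt windows and 30 with at least 30 reads.

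Among windows of 21 and 22 nt reads, 2792 rose and 264 fell of 15548 with DRB1 mutated, at a median log2 change of 0.51. Of the 264 that fell, 124 (47.0%) touched a MIR gene, as did 1.65% of tested windows. MIR169e, MIR156f and the window of MIR2934 and MIR782 fell most. MIR156f had 0 reads in drb1, drb12 and drb14 and 18 in WT (FDR 0.000888). Windows of MIR172d (chromosome 3, 20588001 to 20589000; 0.0332 RPM in WT, 19.4, 11.3 and 16.0 in drb1, drb12 and drb14; FDR 3.85e-08) and MIR171a (8.30 RPM in WT, 126, 26.6 and 401; FDR 3.51e-06) rose. With TMM 144 rose and 415 fell, and with structural reads as library size 220 rose and 256 fell, so the balance of up and down rested on the scaling. The count of 3056 was 415 without WT, 1543 without drb1, 1472 without drb2, 1686 without drb4, 1299 without drb12 and 1190 without drb14. It was 1827 with DESeq2 and 7383 with multi-mapped reads weighted.

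With DRB2 mutated, 63 of 76 miRNAs fell and 0 rose, at a median log2 change of −1.17. miR856 (−3.40, SE 0.38, FDR 0.00121; 5.31 RPM in WT, 0.468, 0.0291 and 0.779 in drb2, drb12 and drb24) and miR840 (−2.84, SE 0.37, FDR 0.00179) fell most. Next came miR853 (−2.18), miR839 (−2.02), miR5026 (−1.81), miR408, a copper miRNA (−1.80), miR822 (−1.67), miR827, which targets the phosphate regulator NLA (−1.66), miR780.1 (−1.64) and miR172e (−1.62). The triggers miR173 (−1.16, SE 0.25, FDR 0.00658) and miR390a (−0.99, SE 0.30, FDR 0.0173) fell about as much as the median. With TMM the median moved to −0.03 and the 2 calls left were miR856 (−2.30, FDR 0.0346) and miR840 (−1.69, FDR 0.0494). There miR173 was at −0.03 and miR390a at 0.17. With structural reads as library size the median was −0.18 and 2 passed. With 2 groups and no covariate edgeR called 0 (6 at unadjusted p under 0.05; DESeq2 called 65 in the additive model). The calls of miR856 (−2.93) and miR840 (−2.37) were lost there. The count was 38 without WT and 15 without drb12. Without drb12 the calls of miR839 (−2.22), miR5026 (−1.54), miR408 (−1.69), miR822 (−1.79), miR172e (−1.21) and miR390a (−0.95) were lost, and without WT those of miR5026 (−1.68), miR172e (−1.36) and miR390a (−0.91).

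By list, 30 of 36 conserved, 31 of 38 less conserved, both DCL4-dependent, 1 of 2 copper, 4 of 6 phosphate and sulphate, all 6 phase-change and both pollen miRNAs fell with DRB2 mutated, with the same counts adjusted over the list alone. With TMM edgeR called 2 less conserved miRNAs and 0 in the other lists (0 at unadjusted p under 0.05; at the main library size DESeq2 called 31 conserved, 2 DCL4-dependent, 2 copper, 4 phosphate and sulphate, 6 phase-change and 2 pollen). At the fixed loci, 21 and 22 nt reads fell at 32 of 40 and rose at 0. TAS1B −1.34, TAS1C −1.24 (SE 0.18, FDR 0.000966), TAS1A −1.16, TAS2 −1.15, TAS3A −1.11 (SE 0.15, FDR 0.000957) and TAS3B −1.04 fell. TAS3C (−0.51) and TAS4 (0.87) did not pass. The other falls were 15 of 16 PPR loci, 8 of 10 other phased loci, 2 of 3 pathway genes (DCL1 and AGO4) and DRB5, with the same counts adjusted over the list alone. With TMM 2 passed, TAS4 upward (2.01) and AT5G38850, a disease resistance gene, downward (−1.23), and the median locus moved from −1.34 to −0.27. With structural reads as library size edgeR called 0 (2 at unadjusted p under 0.05; DESeq2 called 27 in its own fit). The count was 7 without WT, 20 without drb12 and 0 without drb24 (18 at unadjusted p under 0.05), and the 6 TAS calls were lost without drb24 (TAS1B −1.35, TAS1C −1.14, TAS1A −1.25, TAS2 −0.97, TAS3A −1.07, TAS3B −1.03).

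For 24 nt reads at the fixed loci with DRB2 mutated, AT1G12290, a disease resistance gene among the other phased loci, fell (−1.77, SE 0.49, FDR 0.0139). edgeR called 0 of the TAS, PPR, DRB and pathway loci (6, 4, 0 and 0 at unadjusted p under 0.05; DESeq2 called 4, 1, 0 and 0), but 6 of 7 TAS loci fell adjusted over the list alone. Of 29 loci 11 had an unadjusted p under 0.05, and DESeq2 called 6 and blocks 17. With TMM 0 passed (2 at unadjusted p under 0.05). Without WT, drb4, drb12 or drb24 0 passed (1, 8, 3 and 2 at unadjusted p under 0.05), and without drb2 or drb14 13 and 17 did.

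Over the genome, 2696 windows of 24 nt reads rose and 380 fell with DRB2 mutated. Of those that rose 37.9% lay in pseudogenes, 37.6% outside annotated genes and 18.8% in coding exons, near the shares of tested windows (35.4%, 34% and 22.1%). Of those that fell 49.5% lay in coding exons, as did 22.1% of tested windows. The largest rises were at single loci. A window without an annotated gene (chromosome 2, 13702001 to 13703000) had 24.6, 25.3 and 19.2 RPM in drb2, drb12 and drb24 and at most 0.0684 elsewhere (FDR 2.85e-05). DRB2 lies on the same chromosome (start 12133732), so a linked segment is not separated from the loss of DRB2 for this window, in either length class. The same limit holds for AGL48, on this chromosome too. AGL48, a MADS-box gene (chromosome 2, 16794001 to 16795000), had 4.23, 5.21 and 5.23 against 0.0332 RPM in WT (FDR 0.000326), and GSTF14, a glutathione S-transferase gene, 3.25, 15.5 and 2.20 against 0.166 (FDR 0.00139). AT1G63615 (chromosome 1, 23586001 to 23587000) fell from 15.8 RPM in WT to 0.0739, 0.0291 and 0.0835 (FDR 0.00083), and AT5G07310, an ERF-type gene, from 2.22 to 0, 0.0291 and 0 (FDR 0.000431). With TMM, which moved the median window from 0.23 to −0.00, 1138 rose and 756 fell. With structural reads as library size the median was 1.22 and 26737 rose and 93 fell. The count of 3076 was 304 without WT, 1479 without drb2, 1549 without drb4, 910 without drb12, 1993 without drb14 and 1519 without drb24. It was 1993 with blocks and 6903 with multi-mapped reads weighted.

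Windows of 21 and 22 nt reads split nearly evenly with DRB2 mutated, 823 up and 757 down (634 and 1013 with TMM). Of those that fell 70.4% lay in coding exons, as did 27.9% of tested windows, and 127 (16.8%) touched a MIR gene. The window on chromosome 2 from 13702001 to 13703000 (1.43, 1.86 and 0.696 RPM in drb2, drb12 and drb24, 0 in WT; FDR 0.0002) and GSTF14 (0.468, 2.74 and 0.306 RPM, 0 in WT; FDR 0.0002) rose in this class too, and AT1G63615 fell (1.13 RPM in WT, 0, 0.0291 and 0; FDR 0.0002). The count of 1580 was 167 without WT, 798 without drb2, 898 without drb4, 423 without drb12 and 788 without drb24. It was 2745 with multi-mapped reads weighted, and 10829 (10747 up, median 1.12) with structural reads as library size.

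With DRB4 mutated 7 miRNAs rose and 3 fell of 76, at a median of 0.25. miR860 rose most (log2 3.92, SE 0.33, FDR 0.000121). It stood at 34.3 RPM in drb4 and 22.4 in drb24 against 3.35 in WT and 1.63 in drb2, and at 3.58 in drb14 against 0.12 in drb1. miR5026 (2.86, SE 0.44), miR863 (2.85, SE 0.56), miR833a (2.62, SE 0.32), miR852 (2.29, SE 0.42), miR841a, which targets histone H2A genes (2.27, SE 0.61) and miR781a (1.51, SE 0.28) also rose. The 2 DCL4-dependent miRNAs, miR822 (−4.35, SE 0.44, FDR 0.000264) and miR839 (−4.34, SE 0.55, FDR 0.000721), fell, and miR840 fell by 2.88 (SE 0.37, FDR 0.000721). miR839 went from 39.6 RPM in WT to 5.17, 2.46 and 0.334 in drb4, drb14 and drb24. miR173 (0.08, FDR 0.821) and miR390a (0.46, FDR 0.463) did not pass, and miR828, the TAS4 trigger, had at most 2 reads per library.

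By list, 7 less conserved miRNAs rose and 1 fell with DRB4 mutated (10 and 1 adjusted over the list alone; 6 and 1 with TMM), and both DCL4-dependent miRNAs fell. edgeR called 0 conserved, copper, phosphate and sulphate, phase-change or pollen miRNAs, also adjusted over the list alone (0 at unadjusted p under 0.05 in each; DESeq2 called 0 in each). With TMM 9 of the 10 calls were kept, miR841a being lost (2.03, FDR 0.119). Leaving out 1 library ended the calls of miR5026 (2.37) and miR852 (2.11) without drb14 and of miR841a without drb1 (2.03) or drb4 (1.76). With 2 groups and no covariate 5 passed, and miR860 (3.51), miR852 (2.44), miR781a (1.40), miR841a (2.54) and miR840 (−2.39) did not.

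At the fixed loci with DRB4 mutated, 21 and 22 nt reads fell at 10 of 16 PPR loci (11 adjusted over the list alone), most at AT1G63230 (chromosome 1, 23450560 to 23452372; −3.40, SE 0.57, FDR 0.00697; 3.65 RPM in WT and 0.308 in drb4). They rose at the 3 DRB genes tested, DRB3 (1.57), DRB5 (1.42) and DRB2 (1.19), where DESeq2 called 0, and at 2 disease resistance genes, AT5G43740 (1.16) and AT1G12290 (1.11), of which 0 passed adjusted over the list alone. At the 8 TAS loci and 3 pathway genes edgeR called 0 (1 TAS locus at unadjusted p under 0.05; DESeq2 called 0). There TAS1C was at −0.43, TAS2 at −0.10, TAS1A at 0.31, TAS1B at 0.38, TAS3A at 0.03, TAS3B at 0.17, TAS3C at −0.01 and TAS4 at 0.72. TAS1C passed as lower with TMM (−0.53), with blocks (−0.49), with structural reads as library size (−0.62) and without drb12 (−0.49) or drb14 (−0.68). TAS2 passed as lower without drb14 (−0.37) and TAS1B as higher without drb2 (0.54). The pooled lengths moved apart. From WT to drb4, 21 nt reads fell at TAS1B (204.3 to 114.9 RPM), TAS1C (2402.5 to 1047.2) and TAS2 (1188.4 to 682.6). There 22 nt reads rose (36.43 to 207.5, 541.2 to 954.2 and 192.3 to 567.6). Most TAS loci did so in all 3 matched pairs, but 21 nt reads rose at TAS3A in drb14 over drb1 and at TAS3C and TAS4 in drb24 over drb2. The lengths were not tested apart. The 15 calls became 0 without WT (6 at unadjusted p under 0.05), 0 without drb1 (15), 2 without drb4 and 0 without drb24 (3), and 12 with DESeq2.

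The 24 nt reads of the same loci rose with DRB4 mutated, at 14 of 29 and at 7 of 7 TAS loci. These were TAS3C (3.24, SE 0.57, FDR 1.21e-06), TAS1B (2.09, SE 0.41), TAS3A (2.02, SE 0.35, FDR 1.21e-06), TAS1A (1.55), TAS3B (1.52), TAS1C (1.35) and TAS2 (0.88, FDR 0.0299). DRB5 (5.34, SE 0.57, FDR 1.54e-13), DRB3 (3.38) and DRB2 (2.66) also rose, with the PPR locus AT5G16640 (4.45), the auxin receptor gene TIR1 (3.64, SE 0.61) and SPL13A and SPL13B, targets of miR156 (1.60 and 1.63). SPL13A and SPL13B had nearly the same counts in every library (49 reads each in drb14), so their calls are not independent. The pathway genes DCL1 (0.78) and DCL4 (−0.80) did not pass. The counts adjusted over the list alone were the same. Per 100 reads of 21 and 22 nt over the TAS loci there were 19.4 of 24 nt in drb4 and 26.7 in drb24 against 7.70 in WT and 9.0 in drb2. There were 9.23 in drb14 against 2.99 in drb1. The log2 ratio had a mean of −2.57 (SD 0.785, n = 3) with DRB4 mutated and −4.21 (SD 0.817, n = 5) otherwise (two-sided exact permutation p = 0.0536, adjusted 0.188 over 21 tests, higher in all 3 matched pairs). With TMM the median locus moved from 0.88 to −0.53, 5 rose and 5 fell. Of the TAS loci TAS3C passed (2.02, FDR 0.0162) while TAS1C (−0.06) and TAS2 (−0.56) changed sign. Without WT 9 of 29 passed. Calls were lost for TAS3B without WT (1.37), for TAS1C without WT (1.32) or drb24 (1.31), and for TAS2 without WT (0.97), drb1 (0.73), drb12 (0.79) or drb24 (1.04), with blocks (0.79) and with structural reads as library size (0.69).

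**Figure D3:**
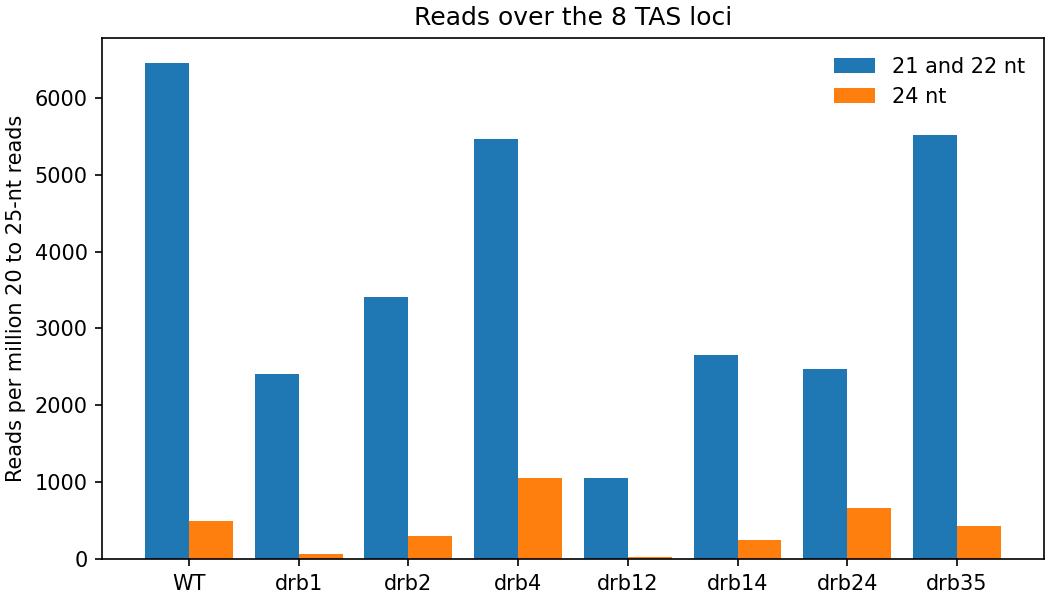
RPM of 21 and 22 nt (1 bar) and of 24 nt (1 bar) summed over the 8 TAS loci, per library, with 1 library per genotype and no error bars. WT has 6458.1 RPM of 21 and 22 nt and drb12 1061.8, and drb4 (19.4) and drb24 (26.7) have more 24 nt reads per 100 reads of 21 and 22 nt than WT (7.70).

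Across the genome, 24 nt reads rose with DRB4 mutated in 1145 windows and fell in 901. Of the windows that rose 874 (76.3%) lay in coding exons, against 22.1% of tested windows. Of those that fell 33.6% lay in coding exons too, 35.8% outside annotated genes and 14.5% in pseudogenes. The shares of tested windows were 22.1%, 34% and 35.4%. Over all 6801 tested windows of coding exons the sum stood at 75893.6 RPM in drb4 and 92117.8 in WT, at 89100.8 in drb14 and 107084.9 in drb1, and at 113567.2 in drb24 and 105692.6 in drb2. RPA1A, a subunit of replication protein A (chromosome 2, 2586001 to 2587000), had 6.88, 11.7 and 4.34 RPM in drb4, drb14 and drb24 and 0 in WT (FDR 3.97e-05), and RLP42, a receptor-like protein gene (chromosome 3, 9117001 to 9118000), 2.46, 3.22 and 1.28 and 0 in WT (FDR 0.0013). A window without an annotated gene (chromosome 3, 23130001 to 23131000) fell from 25.3 RPM in WT to 0.0684, 0 and 0.0278 (FDR 0.00113). It lies near DRB4 (start 23225526), so a linked segment is not separated from the loss of DRB4 for this window. The F-box gene AT3G24700 fell from 2.26 to 0.0684, 0.0397 and 0.0556 (FDR 0.0013). With TMM 1373 rose and 824 fell. The balance turned with a minimum of 30 reads (297 up, 549 down), with structural reads as library size (972 up, 1651 down) and without drb24 (1213 up, 1756 down). The count was 997 without WT and 538 without drb14.

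Reads of 21 and 22 nt fell in 6091 windows and rose in 347 with DRB4 mutated, at a median log2 change of −0.69. Of those that fell 44.9% lay in pseudogenes and 29.1% outside annotated genes, against 30.5% and 31% of tested windows. Of those that rose 83.9% lay in coding exons (27.9% of tested windows) and 56 touched a MIR gene. The windows of NRT1.9, a nitrate transporter gene that overlaps MIR837 (chromosome 1, 6520001 to 6522000; 9.82, 2.98 and 4.23 RPM in drb4, drb14 and drb24 against 0.365 in WT from 6521001, FDR 2.41e-07) and of AT4G38760, which overlaps MIR8178 (2.91, 6.40 and 1.67 against 0.0332 RPM, FDR 2.41e-07) rose. AGL91, a MADS-box gene, fell from 0.531 RPM in WT to 0 in the 3 libraries (FDR 2.44e-05), and TPS4, a trehalose phosphate synthase gene, from 0.631 to 0, 0 and 0.0278 (FDR 2.42e-05). With TMM the median was 0.01, and 1079 rose and 1670 fell. In all 4097 passed with at least 30 reads and 11810 with multi-mapped reads weighted.

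Against WT, miRNA levels of each mutant are ratios with no replicate check, given with 95% counting intervals. The median of 76 guides was −1.80 (log2) in drb1 (66 lower), −1.10 in drb2 (72 lower), 0.27 in drb4 (63 higher), −2.71 in drb12 (74 lower), −1.42 in drb14, −1.01 in drb24 and −0.26 in drb35 (54 lower). miR166a, which targets class III homeodomain leucine zipper genes and took the most WT reads, stood at 0.431 of WT in drb1, 0.533 in drb2, 1.16 in drb4, 0.332 in drb12, 1.03 in drb14, 0.321 in drb24 and 1.15 in drb35. Its sister miR165a stood at 0.127 in drb1 and 0.0925 in drb12, and miR159a at 0.0549 in drb1, 0.0209 in drb12, 0.0604 in drb14 and 0.958 in drb4. The lowest ratios were miR781a in drb1 (0.0138; 0.00445 to 0.0326), miR856 in drb2 (0.0881; 0.0517 to 0.142), miR822 in drb4 (0.0706; 0.0463 to 0.104), miR856 in drb12 (0.00548 on 1 read; 0.000138 to 0.031), miR173 in drb14 (0.0228) and miR840 in drb24 (0.00821 on 1 read; 0.000206 to 0.0468). The highest were miR840 in drb1 (1.75; 1.37 to 2.25), miR395b, which targets sulphate assimilation genes, in drb2 (3.08; 1.98 to 4.98), miR860 in drb4 (10.2; 8.33 to 12.7) and drb24 (6.69; 5.43 to 8.31) and miR168a, which targets AGO1, in drb14 (2.08; 2.05 to 2.11). In drb35 miR839 (1.82; 1.70 to 1.95) and miR399a (1.49) were highest, and miR160a (0.483; 0.452 to 0.516) and miR163 (0.559) lowest. The DCL4-dependent list had a median of −3.37 in drb4, at percentile 0.155 of random lists of like level, −4.66 in drb14 (percentile 0.345) and −6.12 in drb24 (0.415), and the less conserved list −2.48 in drb1 (percentile 0.44). These medians follow the library size: with structural reads as library size they were −2.07 in drb1, −0.10 in drb2, −0.02 in drb4, −2.12 in drb12, −1.91 in drb14, −0.16 in drb24 and −0.16 in drb35.

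Between the double mutants and their single mutants, the median guide was at −1.26 (log2) in drb12 over drb1 and −1.82 over drb2, at 0.49 in drb14 over drb1 and −1.64 over drb4, and at 0.18 in drb24 over drb2 and −1.21 over drb4, where 76 of 76 were lower. miR860 was 29.8 times higher in drb14 than in drb1 (11.3 to 112; 90 and 4 reads) and 13.8 times higher in drb24 than in drb2 (10.7 to 18.0). miR396b, which targets growth-regulating factors, stood at 2.71 in drb14 over drb1, and miR166a at 2.39 there but 0.603 in drb24 over drb2. miR398b, which targets copper superoxide dismutase, stood at 0.0472 in drb24 over drb4, 0.0749 in drb14 over drb4 and 0.142 in drb12 over drb2. These ratios have no replicate check and follow the scaling. In the order drb12 over drb1 and drb2, drb14 over drb1 and drb4, and drb24 over drb2 and drb4, the medians were −0.41, −2.23, 0.27, −1.83, 0.03 and −0.06 with structural reads as library size. With DESeq2 size factors, which bring the median miRNA near 0 by construction, they were −0.07, −0.01, 0.09, 0.08, −0.00 and 0.11.

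Summed over the 8 TAS loci, 21 and 22 nt reads stood at 0.373 of WT in drb1 (0.370 to 0.376), 0.527 in drb2, 0.847 in drb4, 0.164 in drb12, 0.412 in drb14, 0.384 in drb24 and 0.853 in drb35, ratios without a replicate check. Scaling turned some of them. With DESeq2 size factors the log2 ratio was 0.32 in drb1, 0.21 in drb2, 0.33 in drb12 and 0.07 in drb14. These factors bring the median miRNA near 0 by construction, which lifts other classes where most miRNAs fell, so they do not decide whether the sum fell. With structural reads as library size it was 0.07 in drb2 and −1.69 in drb1. Of the loci that miR173 triggers, TAS1B stood at 0.0524 in drb1, 0.0142 in drb12 and 0.0655 in drb14, but 0.591 in drb24. TAS3A stood at 0.996 in drb1, 1.18 in drb14, 0.485 in drb2 and 0.464 in drb12. TAS1C was at 0.680 in drb4 and 0.299 in drb24. TAS4, whose siRNAs target MYB genes of anthocyanin synthesis, had 0 reads in drb12 and 36 in WT (a ratio of at most 0.0731 with the floor of 3 reads) and was at 4.19 in drb24 (2.92 to 6.17). Between mutants the sum stood at 0.441 in drb12 over drb1, 0.312 over drb2, 1.11 in drb14 over drb1, 0.486 over drb4, 0.728 in drb24 over drb2 and 0.453 over drb4. The ta-siRNA siR255 stood at 0.184 of WT in drb1, 0.557 in drb2, 0.3915 in drb4, 0.0601 in drb12, 0.0804 in drb14, 0.175 in drb24 and 0.858 in drb35. The TAS3 siRNA tasiR-ARF (variant A) stood at 0.578 in drb1, 0.912 in drb14 and 0.250 in drb24, and variant B (64 reads in WT) at 1.086 (0.770 to 1.538), 0.580 and 0.406. The repeat siRNA siR1003 stood at 0.872 to 1.17 in all 7 mutants. The repeat siRNA siR02 had 0 reads in WT and at most 1 in a mutant, so no ratio is given.

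The median log2 ratio of passenger to guide reads over 26 pairs was −5.99 in WT and −6.70 (drb1) to −5.40 (drb12) in the mutants. The median difference from WT lay between −0.24 (drb14) and 0.14 (drb24). Over 35 miRNAs the median share of reads at the annotated 5′ end was 96.8% in WT and 96.8 to 97.3% in the mutants, with 4 miRNAs lower than WT by over 10 points in drb14, 2 in drb1 and drb24, 1 in drb4 and drb12, and 0 in drb2 and drb35. These comparisons were not tested.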

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

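The test of sense share and the label deals of the fixed loci were set before their results were seen; all other tests reported here, with their thresholds, were chosen only after the result was seen.

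With DRB2 mutated in drb2, drb12 and drb24, 63 of 76 miRNAs fell relative to reads of 20 to 25 nt. A larger share of 24 nt reads alone is argued against as the whole cause. It lowered the share of the other lengths by 0.29, 0.14 and 0.55 (log2) in drb2 over WT, drb12 over drb1 and drb24 over drb4. Per reads of those lengths the 63 miRNAs still had medians of −0.90, −1.21 and −0.61. Those lengths include 23 nt reads, also more numerous in drb2 (6038464, 3498526 in WT), drb12 (5399553, 4526236 in drb1) and drb24 (5443332, 3013816 in drb4). Dilution by 23 and 24 nt reads together was not tested. A shared difference in RNA quality or size selection cannot be told apart from the genotype, because the structural RNA share was lower in the same 3 libraries (difference −4.63 percentage points) and each genotype has 1 library. For the same reason the median of −0.18 with structural reads as library size does not decide, and loss of DRB2 itself stays open. For the 63 calls, 1 of 99 label deals gave as many, the real one (highest other 47). A deal that kept DRB2 on its own 3 libraries but moved the other labels called 0, so the deals do not exclude chance.

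With DRB4 mutated in drb4, drb14 and drb24, 7 less conserved miRNAs rose. Scaling by reads of 20 to 25 nt is argued against, since 6 of the 7 rose with TMM, and so are a shift of read ends (7 of the 7 rose with ends within 2 nt) and reads shared with other positions (2 of the 7 have more than 1 genome position). For the 10 miRNA calls of this allele, 7 of 98 label deals, the real one included, called as many. Of these, 55 on the libraries with DRB2 mutated and 46 on those with neither DRB1 nor DRB2 mutated follow the other alleles. The 29 on WT, drb14 and drb35 and 29 on drb1, drb14 and drb24 match no allele. Each deal moves the labels of all alleles, so effects of DRB1 and DRB2 can enter these calls too. They do not by themselves show a structure of the samples. Deals that kept DRB4 on its own libraries but moved other labels called 0, so the deals do not decide on chance, which was not excluded. Loss of DRB4 stays open, and a structure of the samples was not excluded.

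With DRB4 mutated, 874 of the 1145 rising windows of 24 nt reads lay in coding exons, though over all 6801 tested coding-exon windows the sum was lower in drb4 (75893.6 RPM; 92117.8 in WT) and drb14 (89100.8; 107084.9 in drb1) and higher in drb24 (113567.2; 105692.6 in drb2). Of the 901 falling windows 303 (33.6%) lay in coding exons too, against 22.1% of tested windows. A chromosome segment linked to DRB4 is argued against as the cause of most of the rising coding-exon windows, since 3.32% of them (29) lay within 2 Mb of the gene. That share was above the 1.07% of tested coding-exon windows, so linkage is not excluded for those 29. Fragments of degraded mRNA are argued against by a median sense share of 51.3%, and replacement of 21 and 22 nt reads by a median change of those of 0.81 (log2; 400 windows tested in both classes). In the rising coding-exon windows, 24 nt reads stood at 12.1 to 17.6 times the mean of 23 and 25 nt reads in the 3 libraries. In the other 5 the ratio was 5.61 to 6.63. The windows were picked for rising 24 nt reads in these same libraries, which favours a higher ratio. The ratio therefore does not decide on a general rise of neighbouring lengths. A bound of 3 set before the test was passed in all 8 and decided nothing. Reads of 23 nt (54528 in the 3, 37342 in the other 5) and 25 nt (17982 and 9041) were also more frequent, less so than those of 24 nt (523338 and 145820). For the 2046 windows called, 2 of 58 label deals gave as many, the real one included (highest other 3358, on the libraries with DRB2 mutated). A deal on the libraries of another allele thus called more than the real one, so the deals do not exclude chance. Loss of DRB4 stays open, and the balance of rising and falling windows turned without drb24.

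Label deals other than the real one that left the tested allele on its own 3 libraries were not counted, a rule set after the counts were seen. The real deal is in every count. Each deal moves the labels of all alleles, so effects of other alleles enter its residual and can lower its calls. For miRNAs, the deals left out called 0 for DRB2, 0 for DRB4, and 43 and 56 for DRB1. The deals therefore do not exclude chance, and their counts are given without a verdict. For miRNAs with DRB1 mutated (58) 1 of 98 deals called as many, the highest other being 55, on drb1, drb2 and drb12. For 24 nt windows with DRB2 mutated (3076) it was 1 of 60, the highest other being 2087, on the libraries with DRB4 mutated. With DRB1 mutated (47) it was 5 of 58, the highest other being 1052, on the libraries with DRB2 mutated. For 21 and 22 nt windows with DRB1 mutated (3056) it was 2 of 58, the highest other being 3174, on drb1, drb2 and drb12. With DRB4 mutated (6438) it was 1 of 58, the highest other being 1511, on the libraries with DRB2 mutated. With DRB2 mutated (1580) it was 4 of 60, the highest other being 6415, on the libraries with DRB4 mutated. For 21 and 22 nt reads of loci it was 3 of 98 for DRB1 (28, highest other 28) and 1 of 99 for DRB2 (32, highest other 24). For DRB4 (15) it was 8 of 98, the highest other being 31, on the libraries with DRB2 mutated. For 24 nt reads of loci it was 1 of 98 for DRB1 (15, highest other 9) and 1 of 98 for DRB4 (14, highest other 12). For DRB2 (1) it was 15 of 99, the highest other being 13, on the libraries with DRB4 mutated. Deals that called several times the real count fell both on the libraries of another allele and on sets of no allele. Effects of the other alleles can enter both kinds, so these deals do not by themselves show a structure of the samples.

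Some guides moved opposite ways in 2 backgrounds of 1 allele, with counting intervals on opposite sides of 1, and these differences were not tested. For loss of DRB1 there were 2 between drb1 over WT and drb12 over drb2 (miR395b, 1.95 and 0.375, and miR839), 4 between drb1 over WT and drb14 over drb4, and 1 between drb12 over drb2 and drb14 over drb4 (miR396b). For loss of DRB2 there were 2 between drb2 over WT and drb12 over drb1 (miR395b, 3.08 and 0.594, and miR398b, 1.44 and 0.319) and 2 between drb2 over WT and drb24 over drb4. For loss of DRB4 there were 10 between drb4 over WT and drb14 over drb1, 24 between drb4 over WT and drb24 over drb2 (among them the copper miRNAs miR398b, 4.94 and 0.162, and miR408, 2.94 and 0.419, and the sulphate miRNA miR395b, 5.15 and 0.163), and 22 between drb14 over drb1 and drb24 over drb2 (among them miR396b, 2.71 and 0.547).

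Reads without a genome match, which the comparisons do not use, held sequences with at least 10 reads in each of the 3 libraries of an allele and 0 in the other 5. With DRB4 mutated there were 90 of 21 nt, 15 of 22 nt and 546 of 24 nt (together 459, 615 and 349.5 RPM of 24 nt in drb4, drb14 and drb24), with DRB2 mutated 2 of 21 nt, 3 of 22 nt and 126 of 24 nt, and with DRB1 mutated 0 at each length. Of the other sets of 3 libraries, the highest had 8 sequences of 22 nt and 0 of 21 or 24 nt. The MIR171a hairpin gave a 22 nt product away from its annotated ends (chromosome 3, 19073437 to 19073458) at 341.7 RPM in drb14, with 8598 reads there, 3191 in drb1, 790 in drb12 and 140 in WT.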

How the results depend on the processing

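The library sizes of structural reads, all alternatives for fixed loci and those for double over single mutants were chosen after seeing the data; the rest were planned. Of the values that answer a comparison, 65 stayed within the limit used (1.5 times for a count, the counting interval otherwise) and 129 moved under the alternatives other than leaving out a library, and 78 and 42 when 1 library was left out. Of the values of named miRNAs, loci and windows, 764 kept direction and side of the threshold, 79 were no longer past it, 18 came past it, 23 not past it changed sign and 11 called ones reversed; leaving out 1 library gave 1022, 80, 23, 19 and 0. No paired analysis was possible because each group has 1 library and the groups share only number 1; matched backgrounds served as blocks instead. Leaving out a library leaves 2 residual degrees of freedom and some alleles in 2 libraries, whose spread is taken from the others. Depth limits TAS4, miR828 and siR02, and windows near the minimum of 10 reads. A larger library size for a class lowers it by construction. DESeq2 size factors bring the median miRNA near 0 by construction. TMM, computed from the counts under test, likewise moves their typical change toward 0. Its reversals therefore do not decide the direction of those entries. For the other moves the cause was not tested.

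With 2 groups and no covariate, miRNA calls were 37 (DRB1), 0 (DRB2; edgeR, 6 at unadjusted p under 0.05, DESeq2 65 in the additive model) and 5 (DRB4). With TMM, miRNA calls for DRB2 were 2, locus calls 2 (21 and 22 nt, DRB2), 8 (24 nt, DRB1) and 0 (24 nt, DRB2; edgeR, 2 at unadjusted p under 0.05, DESeq2 6), and window calls 74 (24 nt, DRB1), 1894 (24 nt, DRB2), 559 (21 and 22 nt, DRB1) and 2749 (21 and 22 nt, DRB4). TMM reversed miR390a (0.81 for DRB1, 0.17 for DRB2), TAS1C (0.11), TAS3B (1.34) and TAS3C (1.47) in 21 and 22 nt reads for DRB1, TAS3B (0.03) for DRB2, and TAS1C (−0.06) and TAS2 (−0.56) in 24 nt reads for DRB4. With DESeq2 size factors DRB2 had 2 miRNA calls, and miR390a (0.93 for DRB1, 0.23 for DRB2) and miR173 (0.07 for DRB2) reversed. With structural reads as library size DRB2 had 2 miRNA calls and 0 locus calls in either class (edgeR, 2 and 0 at unadjusted p under 0.05, DESeq2 27 and 6), and windows numbered 149 (24 nt, DRB1), 26830 (24 nt, DRB2), 476 (21 and 22 nt, DRB1) and 10829 (21 and 22 nt, DRB2). The DESeq2 Wald test gave 6 loci (24 nt, DRB2), 463 windows of 24 nt and 1827 of 21 and 22 nt (DRB1). Blocks gave 17 loci (24 nt, DRB2) and 433 (DRB1) and 1993 (DRB2) windows of 24 nt. At least 30 reads gave 30 (DRB1) and 846 (DRB4) windows of 24 nt and 4097 of 21 and 22 nt (DRB4), with fewer windows tested. Windows of 500 nt gave 90 of 24 nt (DRB1). Multi-mapped reads weighted gave 6903 windows of 24 nt (DRB2) and 7383, 2745 and 11810 of 21 and 22 nt (DRB1, DRB2, DRB4).

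Median log2 ratios to WT of miRNAs and of the TAS sum were, in the order drb1, drb2, drb4, drb12, drb14, drb24, drb35: with DESeq2 size factors −0.06, 0.03, −0.10, 0.23, −0.07, −0.06, 0.01 and 0.32, 0.21, −0.61, 0.33, 0.07, −0.43, 0.04; with structural reads −2.07, −0.10, −0.02, −2.12, −1.91, −0.16, −0.16 and −1.69, 0.07, −0.53, −2.02, −1.76, −0.53, −0.13; with 24 nt reads −1.99, −1.35, 0.30, −3.00, −1.53, −1.40, −0.22 and −1.61, −1.18, −0.20, −2.90, −1.39, −1.77, −0.19; with all reads −1.87, −0.94, 0.19, −2.62, −1.56, −0.89, −0.23 and −1.49, −0.76, −0.32, −2.52, −1.42, −1.27, −0.20. Double over single mutants (drb12 over drb1 and drb2, drb14 over drb1 and drb4, drb24 over drb2 and drb4) had miRNA medians of −0.07, −0.01, 0.09, 0.08, −0.00 and 0.11 with DESeq2 size factors and −0.41, −2.23, 0.27, −1.83, 0.03 and −0.06 with structural reads. With end variants the miRNA medians of the first 6 were −1.68, −1.02, 0.28, −2.77, −1.34 and −0.94. With 21 nt reads alone the TAS sum was −0.94 (drb2), −0.76 (drb4), −2.63 (drb12), −1.49 (drb14), −1.98 (drb24) and −0.25 (drb35). Outside structural and organelle RNA the 24 nt share was 45.98% in WT, then 51.57, 55.92, 44.0, 56.53, 48.08, 60.9 and 44.49%, and among distinct sequences 41.59%, then 39.4, 43.83, 44.3, 41.75, 43.92, 45.91 and 41.72%.

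Leaving out each library in turn gave, for DRB1, DRB2 and DRB4, 47 to 62, 15 to 63 and 8 to 14 miRNAs; 22 to 30, 0 to 35 and 0 to 21 loci of 21 and 22 nt; 8 to 18, 0 to 17 and 9 to 17 loci of 24 nt; 16 to 435, 304 to 3163 and 538 to 2969 windows of 24 nt; and 415 to 4249, 167 to 1581 and 4642 to 6433 windows of 21 and 22 nt.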

Other observations

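MIR precursors had a larger median share of reads off the annotated register where DRB1 was mutated. Over 43 precursors the median share of reads more than 2 nt from an annotated end was 2.83% in WT and 8.78% in drb1, 5.57% in drb12 and 8.18% in drb14, against 2.58 to 3.21% in the other 4 mutants. In MIR824, whose miRNA targets the MADS-box gene AGL16, the share went from 0.395% in WT to 24.9, 23.3 and 28.2% in drb1, drb12 and drb14, and in MIR172d, of the family that targets AP2-like genes, from 3.11% to 40.7, 34.95 and 41.4%. Both were chosen after their values were seen, and these shares were not tested. By over 10 points, 6, 6 and 8 precursors were higher than WT in drb1, drb12 and drb14, and 1, 3 and 1 were lower. A share also rises where reads on register fall, and most miRNAs fell with DRB1 mutated. The shares alone do not show that off-register products rose.

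TIR1, an auxin receptor gene whose 24 nt reads rose with DRB4 mutated, lies on chromosome 3 as DRB4 does (starts 23273065 and 23225526), so a linked segment is not separated from the loss of DRB4 for this gene.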
